A study of Mus musculus with 2 samples.

How the data were processed

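Single-cell RNA sequencing had been run on mouse retinas after lipopolysaccharide (LPS, 0.5 µg per eye, per the labels) was placed in the vitreous. There were 2 libraries, 1 per group, each from 6 pooled retinas per the labels' protocols: a control library (Atg5fl/fl, a floxed Atg5 allele without Cre) and a knockout library (the same allele with GLAST-CreER, a tamoxifen-driven Cre of Müller glia). Per the labels, only the knockout group also received 4-hydroxy-tamoxifen, so genotype, Cre and drug go together. The sexes, the delay between injection and harvest and the processing days were not given in the sources used here.

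The deposited matrices held raw UMI counts per gene and cell barcode, which the authors had made with Cell Ranger 6.0.0 per the file headers. Retinas were dissociated with papain and made into 10x Genomics 3' libraries per the labels' protocols, and reads were mapped to mm10 per the series' design text. Seurat 5.2.1 appeared in the submitters' processing notes. The annotation release was not given in the sources used here. The files listed 32285 features, of which 40 repeated a symbol already listed, and the first of each such symbol was used. The coordinates of Atg5 were read from GENCODE annotation of the same build. No file gave cell types, so cells were clustered anew, and differences from the study's own clusters may come from that.

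Cells were kept with under 25% mitochondrial UMIs and at least 500 genes, the study's stated filter. This kept 8274 of 8690 control barcodes and 4662 of 5229 knockout barcodes. Both libraries were merged in R 4.3.3 with Seurat 5.3.0: log-normalisation, 2000 variable genes, 11 principal components and clustering at resolution 1.0, as the design text states, with seed 1. Clusters outside the neurons were clustered again in the same way. A cluster was named from 21 marker lists fixed before the data were examined. It was named where at least 3 markers were detected (at least 10 UMIs each), where its best class scored at least 1 and led the next class by at least 1 (the mean log2 fold of the class's markers over the median cluster, with 5 CPM added), and where its top 10 genes by fold did not hold more markers of another class. These thresholds were set after the data were seen. They kept 8 clusters unnamed, which held 2494 control cells (30.1%) and 1196 knockout cells (25.7%). Müller glia-like cells were clustered once more at resolution 0.4.

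Doublets were looked for with Scrublet, as run in scanpy 1.11.5, per library. Its automatic threshold called 1 control cell (0.0121%) and 4 knockout cells (0.0858%), which means that the caller has not worked here, and no cell was removed in the main values. An alternative, chosen after the data were seen, left out the 548 control and 174 knockout cells with the highest scores, the numbers expected at a rate of 0.8% per 1000 cells.

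UMIs were summed per library and class and given as CPM (each gene's part of all UMIs of that class), with an exact Poisson 95% interval. Ratios are knockout over control, with an exact conditional binomial 95% interval, and shares of cells have exact binomial (Clopper-Pearson) 95% intervals. Intervals of list medians came from 1000 Poisson redraws of the counts. All these intervals cover counting error only. With 1 library per group there was no test between groups, no p-value and no count of changed genes, and no difference has a replicate check. Log2 ratios had 0.5 added to both counts. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. TMM factors for an alternative scaling came from edgeR 4.0.16.

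The named genes followed a rule fixed in advance. Eligible genes had at least 100 UMIs over both libraries in the class, were not predicted (Gm, Rik), mitochondrial, ribosomal or haemoglobin genes, and had a CPM at least as high in the class as outside it in the library where they were higher. Named were the 12 largest and 12 smallest ratios in Müller glia-like cells, and the 3 largest and 3 smallest in each other class with at least 100 cells in each library. In each list, among members with at least 100 UMIs in Müller glia-like cells, the largest and smallest ratio and the 2 highest CPM were named. The genes always named included Atg5, Slc1a3, Glul, Rlbp1, Gfap, Vim, Sqstm1, Lcn2, Ccl2, Cxcl10, B2m, C3, Xist and Ddx3y. Because several of the 24 genes rested on a few cells, 8 abundant genes per side were added after the values were seen: at least 1000 UMIs, and a UMI in at least 25% of Müller glia-like cells of a library.

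The 23 gene lists, fixed in advance, were autophagy machinery, autophagy receptors, lysosome, NRF2 targets, NF-κB response, chemokines and cytokines, type I interferon response, interferon gamma and antigen presentation, complement, inflammasome and lytic cell death, reactive gliosis, Müller glia homeostasis, neurogenic reprogramming, unfolded protein and integrated stress response, early response and dissociation genes, heat shock, nuclear oxidative phosphorylation, mitochondrially encoded, glycolysis, cholesterol synthesis, cell cycle, extracellular matrix and remodelling, and sex-linked genes. Of their members, Cxcl11, Mx1, Mx2, Ctgf and Cyr61 did not match a symbol of the files. A member was measured at 30 UMIs or more over both libraries, and called higher or lower at a ratio of 1.5-fold or more. Each list's median log2 ratio was placed as a percentile among 10000 random lists of the same size, each member drawn from the 200 genes nearest in mean expression. A list is called apart at or below percentile 2.5 or at or above 97.5, as a description of these libraries and not as a test.

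The ratio and list steps were tested on simulated data made from the Müller glia-like sums. Over 10644 genes with 200 changed at random, the interval lay on the right side of 1 for 89.6% of 1.5-fold changes and for all 2-fold and 4-fold changes, and it covered 1 for 95.3% of unchanged genes. In 50 simulations over 13449 genes, a list shifted 1.5-fold stood at percentile 100 each time, and 4.45% of unshifted lists fell outside the band. Both simulations drew pooled Poisson counts without cells. They check the computation, and not whether the intervals or percentiles hold for counts that clump in single cells.

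The alternatives were a stricter cell filter (under 10% mitochondrial UMIs, at least 1000 genes), Scrublet calls left out, 20 principal components, resolution 0.5, a per-cell marker call without clustering, a single Müller subcluster, TMM scaling, the mean of per-cell CPM, cells thinned to 5000 UMIs, free RNA taken away, other minimums of UMIs, a 2-fold threshold, a lower subcluster resolution and shares over neurons and glia alone. Free RNA was taken away as the pooled profile of all other cells of the library, scaled until the rod markers fell to 0, in every class compared but rods. This removed 32.5% of control and 35.8% of knockout UMIs in Müller glia-like cells, so it is an upper limit.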

Results

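Cells of LPS-injected mouse retinas were profiled in 1 control library and 1 knockout library, in which Cre had been driven in Müller glia to delete Atg5, a gene needed to form autophagosomes. The control library held 43669961 UMIs in 8690 barcodes and the knockout library 50676223 UMIs in 5229 barcodes. Among cells kept, the median depth was 1396 UMIs in the control and 6808 in the knockout library, a gap that goes with the mix of cell types described next. Each value below comes from 1 library per group, so none has a replicate check, and intervals cover counting error only.

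The first comparison asked which cells each library held. Rod-like cells made up 44.5% (95% interval 43.5 to 45.6) of control cells and 11.7% (10.8 to 12.7) of knockout cells. The neurons of the inner retina took larger shares in the knockout library: bipolar-like cells 19.3% against 6.93%, amacrine-like cells 20.3% against 6.53%, and retinal ganglion-like cells 1.72% against 0.471%. Müller glia-like cells, the glia that span the retina, were 12.6% (11.7 to 13.6) of knockout and 4.99% (4.53 to 5.48) of control cells. Set against bipolar-like cells, however, they were about as frequent in both libraries, at 72.1 per 100 bipolar-like cells in the control and 65.3 in the knockout library. Rod-like cells numbered 643 and 60.6 per 100 bipolar-like cells, and cone-like cells 19.7 and 10.7.

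Infiltrating neutrophil-like cells were 2.70% (2.36 to 3.07) of control and 3.52% (3.01 to 4.09) of knockout cells, and monocyte and macrophage-like cells 1.14% (0.919 to 1.39) and 1.09% (0.816 to 1.44). Horizontal-like cells were 0.375% and 0.837%, cone-like cells 1.37% and 2.06%, endothelial-like cells 0.665% and 1.07%, and pericyte-like cells 0.157% (13 cells) and 0.0644% (3 cells). Unnamed clusters held 30.1% of control and 25.7% of knockout cells. The largest of them, cluster 1, was led by lens crystallins with rod genes behind them and held 23.5% of control and 9.72% of knockout cells; rod-like cells together with it came to 68.1% and 21.4%. Over named neurons and glia alone, the Müller glia-like shares were 7.66% in the control and 18.4% in the knockout library. Rod-like cells were shallow, with a median of 1119 UMIs in the control and 1031 in the knockout library, so the shares also depend on where barcodes stop counting as cells.

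**Figure D1:**
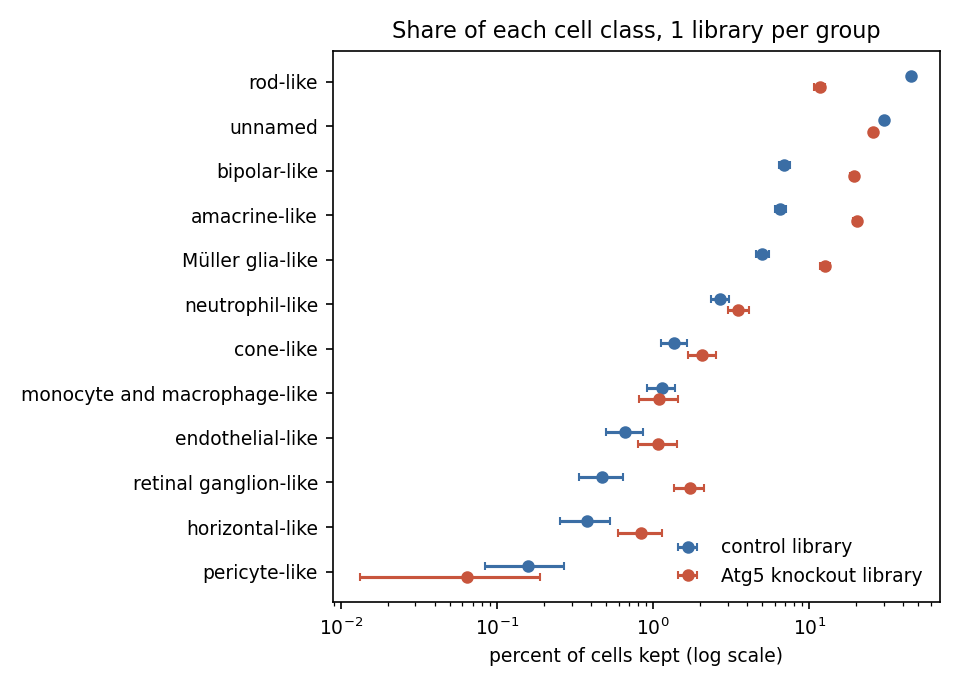
Share of kept cells in each class (x axis, percent on a log scale) for the control library (blue) and the Atg5 knockout library (red), with points for the share and bars for the exact binomial 95% interval. Rod-like cells stand at 44.5% and 11.7%, and Müller glia-like cells at 4.99% and 12.6%.

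Atg5 itself (ENSMUSG00000038160, chromosome 10, 44268358 to 44364291 on mm10) was not lower beyond counting error in Müller glia-like cells of the knockout library. It had 135 UMIs in the control, or 20.5 CPM (17.2 to 24.3), and 220 UMIs in the knockout library, or 18.6 CPM (16.2 to 21.2), a ratio of 0.905 (0.727 to 1.13). Bipolar-like (ratio 0.888) and amacrine-like cells (0.905), which the Cre driver does not target, gave similar values, and the lowest ratio among classes with UMIs in both libraries was 0.381 (0.203 to 0.667), in monocyte and macrophage-like cells. The tag counted here lies at the 3' end of the transcript, and where it lies outside the deleted part it stays countable after deletion. The value therefore checks neither the deletion nor the labels.

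The main comparison was of Müller glia-like cells, 413 control and 588 knockout cells with 6571533 and 11837657 UMIs. Several genes of the resting Müller cell were lower in the knockout library. Glul, the glutamine synthetase that clears glutamate, stood at 1580 CPM (1550 to 1611) in the control and 829 CPM (812 to 845) in the knockout library, a ratio of 0.524. Rlbp1, which carries retinoids of the visual cycle, had a ratio of 0.484 (0.456 to 0.515), while the glutamate transporter Slc1a3, at 0.758 (0.734 to 0.783), stayed within 1.5-fold. Cdkn1a, the cell cycle inhibitor p21, was the most abundant gene among those with the largest ratios, at 335 CPM (325 to 346) in the knockout against 108 CPM (100.4 to 116) in the control library. Genes of the acute inflammatory response were at high levels in both libraries: Lcn2, a secreted siderophore binder, had 27187 and 23859 CPM in control and knockout, and Ccl2, a monocyte-attracting chemokine, 1515 and 1626 CPM.

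Control and knockout Müller glia-like cells were spread differently over the clusters: among the clusters of non-neuronal cells, cluster 5 held the largest share of the control cells of the class (31.2%) and cluster 1 that of the knockout cells (36.9%). The median depth was 14689 UMIs per control and 20198 per knockout cell. RNA of other cells differed too. In Müller glia-like cells the rod markers summed to 2215 CPM in the control and 785 CPM in the knockout library (ratio 0.354, 0.345 to 0.364), the neutrophil markers to 290 and 92.3 CPM (0.319, 0.296 to 0.344), the monocyte and macrophage markers to 50.1 and 50.8 CPM, the lens markers to 5.33 and 9.12 CPM (1.71), and the erythroid markers to 6.39 and 1385 CPM, of which 96.1% of the knockout UMIs lay in 4 cells. The unnamed non-neuronal cluster 10, led by Müller genes with the neutrophil gene S100a8 among them, was not counted in this class. It held 18 control and 61 knockout cells, so neutrophil RNA may have been left out mainly on the knockout side. TMM scaling, which assumes that most genes are alike, moves every log2 ratio here by 0.20 towards the knockout library.

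The 12 largest ratios were of Ccl20, Cxcl9, Mmp3, Spp1, Gdf15, Il11, Bicdl2, Tmem88, Crybb3, Prkg2, Ttc23l and Cdkn1a. Several rested on few cells. The chemokine Ccl20 had a ratio of 32.1 (12.4 to 119) from 231 knockout UMIs in 5 cells, 167 of them in 1 cell, and Cxcl9, a T cell attractant, 13.6 (5.15 to 50.9) from 98 UMIs in 9 cells. The matrix protease gene Mmp3 (9.92, 5.91 to 18.0) had UMIs in 21 knockout cells, and Spp1, osteopontin (7.31, 4.82 to 11.6), in 17, with 134 of 316 UMIs in 1 cell. With the per-cell marker call both turned, to 0.585 and 0.808, as did Spp1 in subcluster 0 alone (0.420) and Mmp3 in subcluster 1 alone (0.196). Crybb3, a crystallin, had a ratio of 4.18 (3.43 to 5.13), but 530 of its 858 knockout UMIs lay in 1 cell. More widely seen were Gdf15, a stress-induced cytokine, at 37.6 against 6.85 CPM (5.49, 4.03 to 7.64) in 95 knockout cells, and Il11, a cytokine of the interleukin-6 family, at 32.9 against 7.30 CPM (4.51, 3.34 to 6.22) in 84. Tmem88 (4.20, 3.19 to 5.63) had UMIs in 226 knockout cells, Bicdl2 (4.27, 2.76 to 6.92) in 117, Prkg2 (3.82, 2.55 to 5.96) in 75 and Ttc23l (3.49, 1.97 to 6.64) in 37.

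The 12 smallest ratios were of Gpc5, Prkag3, Etnppl, Mmp12, Shisal2b, Hes5, Agmo, Kif11, Car14, Folh1, BC055402 and Col9a1. Hes5, a Notch target of progenitors and glia, stood at 72.6 CPM (66.2 to 79.4) in the control and 12.4 CPM (10.5 to 14.6) in the knockout library, a ratio of 0.171, but 1.37 in subcluster 0 alone and 11.5 in subcluster 1 alone. Car14, a carbonic anhydrase of the Müller cell membrane, was at 107 and 22.5 CPM (ratio 0.211, 0.182 to 0.243), and the collagen gene Col9a1 at 82.3 and 18.9 CPM (0.230, 0.196 to 0.269). Prkag3 (0.0871), Etnppl (0.140), Shisal2b (0.157), Agmo (0.193), Kif11 (0.200), Folh1 (0.220) and BC055402 (0.223) made up most of the rest. In subcluster 1 alone Car14 (1.01), Etnppl (1.47), Shisal2b (1.76) and Agmo (1.47) lay above 1. Such ratios within a subcluster were given no interval. They may rest on few UMIs, since Etnppl and Agmo came out equal. The values of Gpc5 (0.0526, with 93 of its 95 control UMIs in 1 cell) and Mmp12 (0.141, with 332 of its control UMIs in 1 cell) describe single cells. Without the 5 cells that held most of each gene, an alternative chosen after the data were seen, the ratio of Gpc5 turned to 4.78.

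Among abundant genes, a set added after the values were seen, the larger ratios after Cdkn1a were of the transcription factor Ets1 (2.83, 2.48 to 3.23), the chromatin protein Hmga2 (2.64), Sertad2 (2.51), Srxn1 (2.49), the growth arrest gene Gadd45b (2.46, at 926 against 376 CPM), the histone demethylase Kdm6b (2.44) and Sertad1 (2.35). The smaller ratios were of Spc25 (0.239, at 57.3 against 240 CPM), the growth factor Ptn (0.247), the transporter Abca8a (0.260), Dgkb (0.320), Nin (0.373), the fatty acid binder Fabp5 (0.376), Cdon (0.393) and Abca8b (0.399). Fabp5 turned to 1.66 in subcluster 0 alone and Abca8b to 1.19 in subcluster 1 alone.

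**Figure D2:**
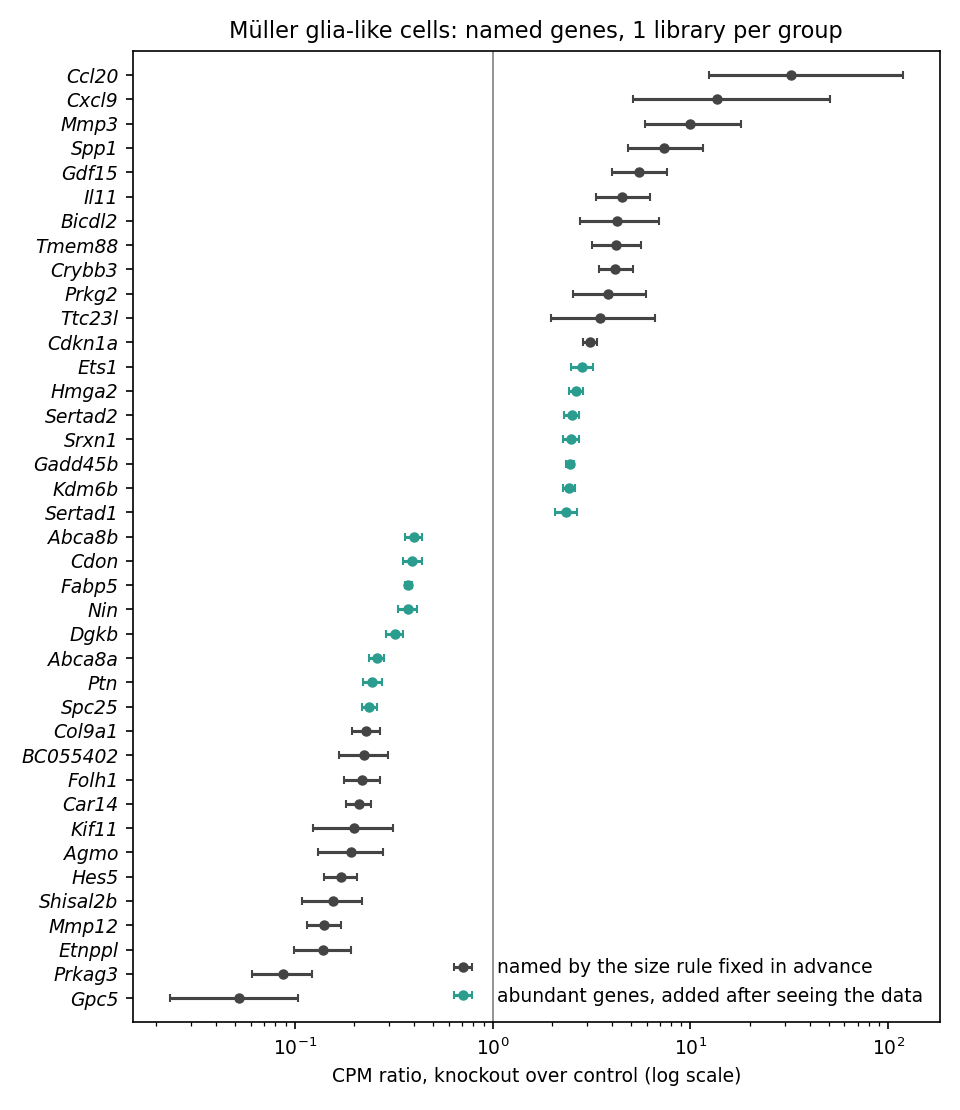
Ratio of CPM in Müller glia-like cells, knockout over control library (x axis, log scale), for the genes with the largest and smallest ratios by the rule fixed in advance (grey) and for abundant genes added after seeing the data (green), with exact conditional binomial 95% intervals as bars. Ratios run from 32.1 for Ccl20, seen in 5 knockout cells, to 0.0526 for Gpc5, held almost wholly by 1 control cell.

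Of the fixed lists, Müller glia homeostasis stood furthest apart. Of its 32 measured members, 12 were at least 1.5-fold lower, 1 (Id2, an inhibitor of differentiation factors, ratio 1.56) was higher and 19 lay between. The median log2 ratio was -0.48, at percentile 0 of matched random lists. Lower members were Hes5, Car14, Abca8a, Glul and Rlbp1, with the ratios given above (though Hes5 lay above 1 within subclusters 0 and 1, and Car14 within subcluster 1). Glul and Rlbp1 stayed within 1.5-fold in subclusters 0 and 1, but not in all subclusters. Glul was at 921 against 1176 CPM in subcluster 0 and 736 against 830 CPM in subcluster 1, and Rlbp1 at 229 against 335 and 76.8 against 111 CPM. In subcluster 2 (16 knockout cells) Glul was at 755 against 3220 CPM and Rlbp1 at 128 against 751 CPM. In subcluster 3, of shallow cells, they were at 615 against 1850 and 223 against 295 CPM. In subcluster 4 they were at 573 against 684 and 61.3 against 174 CPM. Over all Müller glia-like cells the most abundant members, Cp (0.895) and Clu (1.04), lay near 1. Within a single subcluster the median was nearer to 0, at -0.25 in subcluster 0 and -0.24 in subcluster 1. Part of the list also served as Müller markers, and the rod marker RNA named above was lower in the same cells.

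Reactive gliosis genes were not uniformly higher. Of 34 measured, 6 were higher and 2 lower, with a median of 0.10 at percentile 87.2. The list stood above the band with the per-cell marker call (0.32), the mean of per-cell CPM (0.31, 11 higher and 6 lower), thinning (0.23), free RNA taken away (0.20) and the top 5 cells left out (0.15), and below it in subcluster 1 alone (-0.11). The metallothioneins Mt1 (30993 against 17993 CPM, ratio 1.72) and Mt2 (1.66) and the cytokine Lif (755 against 377 CPM, ratio 2.00) were higher in the knockout library, and the endothelin gene Edn2 was lower (0.302, 0.221 to 0.409). The intermediate filament genes Gfap (1.07, 1.00 to 1.14) and Vim (1.08, 1.05 to 1.11) were near 1, and both lay below 1 in subcluster 1 alone.

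Of 32 chemokine and cytokine genes, 12 were higher and 8 lower (median 0.13, percentile 99.85), so the list stood apart with members on both sides. It lay inside the band with the per-cell marker call (0.03) and in subcluster 0 alone (0.10), and turned to -0.13 in subcluster 1 alone, where Cxcl10 was at 0.939. Besides Ccl20, Cxcl9, Spp1, Il11 and Lif, the interferon-induced chemokine Cxcl10 was higher, at 325 against 206 CPM (1.58, 1.48 to 1.68), while Ccl2 (1.07) and the alarmin Il33 (1.14) were near 1. Il1b, a cytokine of activated myeloid cells, was lower (0.178, 0.136 to 0.231), beside the lower neutrophil marker RNA in the same cells (0.319). The unnamed non-neuronal cluster 10, with S100a8 among its genes and mostly of knockout cells, was not counted here and may bear on both. The cholesterol synthesis list also stood apart (21 measured, 2 higher, 1 lower, median 0.19, percentile 99.96). Its members differed little: Hmgcs1 (1.18) and Msmo1 (1.19) were the most abundant, Hsd17b7 the highest (1.55) and Dhcr7 the lowest (0.640). In subclusters 0 and 1 alone and under the per-cell marker call this median lay below 0, and with cells thinned (0.11) it lay inside the band.

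The interferon gamma and antigen presentation list lay at the edge of the band (35 measured, 1 higher, 10 lower, median -0.24, percentile 2.5), and 8 of the 12 alternatives able to move it placed it inside. Socs1, a feedback inhibitor of cytokine signalling, was the highest (2.00, 1.78 to 2.26) and the class II gene H2-Ab1 the lowest (0.182, 0.136 to 0.241), while monocyte and macrophage marker RNA was alike in both libraries. B2m (0.964) and H2-D1 (0.924) of class I were near 1, and B2m lay above 1 under TMM scaling (1.10). Within single subclusters the interferon gamma list stood below the band. It was at -0.42 in subcluster 0 alone (0 of 33 higher, 11 lower) and -0.59 in subcluster 1 alone (1 of 33 higher, 17 lower). The type I interferon list had 1 of 31 higher and 4 lower (median -0.07, percentile 45.3): Ifih1 (1.61), Ifit3 (1.24) and Bst2 (1.15) lay above 1, and Ifi204 (0.418) below it. In subcluster 0 alone 15 of 31 were lower and 0 higher (median -0.56, percentile 0). The list also stood below the band in subcluster 1 alone (-0.14) and above it by the mean of per-cell CPM (0.12).

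The NF-κB list had 3 of 29 higher and 3 lower (median 0.11, percentile 94.9), with Nfkb1 at 637 against 292 CPM (2.18, 2.08 to 2.30), the acute-phase gene Saa3 at 0.381, Cebpd at 1.02 and Lcn2 at 0.878; under TMM scaling Lcn2 came to 1.00. The list stood above the band with free RNA taken away (0.42, 10 of 28 higher and 2 lower), the mean of per-cell CPM (0.26), thinning (0.17) and the top 5 cells left out (0.19), and below it in subcluster 1 alone (-0.19). Complement had 0 of 11 higher and 5 lower (median -0.28, percentile 12.1), with C1ra at 1.14, Cd59a at 0.506 and C3 at 0.890, which TMM scaling brought to 1.02. The list stood below the band with the per-cell marker call (-0.74) and in subcluster 1 alone (-0.37). Inflammasome and lytic cell death had 0 of 13 higher and 3 lower (median -0.02, percentile 94.2), with Ninj1, a mediator of membrane rupture, at 1.32, Il18 at 0.984 and Il1rn at 0.106 beside the lower neutrophil markers. It stood above the band by the mean of per-cell CPM (0.25) and below it in subcluster 1 alone (-0.33).

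Autophagy genes, the pathway Atg5 belongs to, did not stand apart, the machinery and receptor lists under no alternative run. Of 30 machinery genes 1 was higher and 3 lower (median -0.14, percentile 53.9): Wipi2 1.70, Map1lc3a, which encodes an LC3 protein, 1.36, Gabarap 1.09 and Atg4c 0.497. More were lower by the mean of per-cell CPM (1 higher, 10 lower, median -0.36), with free RNA taken away (1 and 11 of 28, -0.31) and with cells thinned (1 and 7). Of 15 receptors 0 were higher and 1 lower (median -0.08, percentile 47.3), with Sqstm1, the receptor p62, at 363 against 293 CPM (1.24, 1.17 to 1.31), Bnip3 at 1.34, Sec62 at 0.906 and Calcoco1 at 0.620. All 29 lysosome genes lay between the bounds (median 0.02, percentile 87.7), among them Neu1 (1.25), Cd63 (1.20) and Ctsl (1.16). With the per-cell marker call the list stood below the band (-0.20). In it 7 were lower and 1 higher with free RNA taken away, 5 of 28 lower with cells thinned and 4 lower by the mean of per-cell CPM. NRF2 targets, of the oxidative stress response, had 2 of 24 higher and 2 lower (median 0.02, percentile 83.2), with the peroxiredoxin repair enzyme Srxn1 at 2.49, the ferritins Ftl1 at 1.33 and Fth1 at 1.17, and Gsta4 at 0.535. They stood above the band in subclusters 0 (0.16) and 1 (0.22) alone, by the mean of per-cell CPM (0.27) and with free RNA taken away (0.16), and below it with the per-cell marker call (-0.21).

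The other lists lay inside the band in the main values. The unfolded protein and integrated stress response had 0 of 25 higher and 1 lower (median -0.02, percentile 59.4; Dnajb9 1.45, Hspa5 0.989, Hsp90b1 0.848, Psat1 0.483). Early response and dissociation genes had 3 of 22 higher and 2 lower (median 0.02, percentile 6.08; Gadd45b 2.46, Fos 0.892, Jun 0.841, Dusp1 0.621). Heat shock genes were all 14 between the bounds (median 0.10, percentile 78.2; Hspa1b 1.40, Hsp90ab1 1.09, Cryab 1.03, Hspb8 0.745). So were all 44 nuclear oxidative phosphorylation genes (median 0.11, percentile 84.3; Ndufa2 1.22, Cox7c 1.12, Cox8a 1.09, Ndufv3 0.859) and all 13 mitochondrially encoded genes (median -0.02, percentile 4.59; mt-Nd2 1.20, mt-Atp6 0.970, mt-Co3 0.943, mt-Nd6 0.823). With the per-cell marker call, early response (0.26) and heat shock genes (0.30) stood above the band and mitochondrially encoded ones (-0.27) below it. In subcluster 0 alone, oxidative phosphorylation (0.12) and mitochondrially encoded genes (0.26) stood above it and unfolded protein (-0.20) and early response genes (-0.36) below, and in subcluster 1 alone unfolded protein (-0.12) and oxidative phosphorylation genes (-0.07) below. Mitochondrially encoded genes also stood below it with 20 principal components (-0.11), the mean of per-cell CPM (-0.18) and free RNA taken away (-0.11).

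Glycolysis had 1 of 20 higher and 2 lower (median 0.09, percentile 72.6), with the lactate carrier Slc16a3 at 1.84, Gapdh at 1.07, Eno1 at 0.918 and Aldoc at 0.532. It stood above the band with the per-cell marker call (0.23) and in subcluster 1 alone (0.38). Cell cycle genes had 1 of 10 higher, Cdkn1a, and 1 lower, Ccnd1 at 0.624 (median -0.01, percentile 68.3), with Ccnd3 at 1.43. Extracellular matrix and remodelling genes had 4 of 22 higher and 2 lower (median 0.08, percentile 97.0), with Timp1, a protease inhibitor of reactive glia, at 6395 against 4965 CPM (1.29), Timp3 at 0.900 and Angptl4 at 0.641. They stood above the band with 20 principal components (0.10), resolution 0.5 (0.18), free RNA taken away (0.18) and a minimum of 100 UMIs (0.23), and in subcluster 1 alone (0.16). Neurogenic reprogramming had 4 of 12 higher and 1 lower (median -0.15, percentile 31.5), with Sox11 at 2.81, Nfib at 0.792, Nfia at 0.759 and Notch2 at 0.653. Of 6 sex-linked genes 0 were higher and 2 lower (median -0.01, percentile 80.0). The list stood above the band with the per-cell marker call (0.31) and in subclusters 0 (0.91) and 1 (0.47) alone, and below it with free RNA taken away (-1.85). Xist, expressed from the inactive X, was at 453 and 219 CPM (0.483), Tsix at 0.461, and the Y-linked Eif2s3y at 1.19 and Ddx3y at 1.16 (0.962 with cells thinned), so both libraries held female and male RNA. In amacrine-like cells Xist went the other way, at 326 and 439 CPM (1.35, 1.27 to 1.42), with Ddx3y at 0.875.

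The counts of members past 1.5-fold depended on the scaling. Under TMM scaling the higher and lower members were 7 and 1 for NF-κB, 8 and 0 for early response, 10 and 2 for reactive gliosis and 4 and 1 for unfolded protein. They were 6 and 1 for extracellular matrix, 4 and 0 for neurogenic reprogramming, 3 and 0 for cell cycle, 3 and 1 for glycolysis and 3 and 2 for NRF2 targets. They were 2 and 0 for heat shock and for cholesterol synthesis, 2 and 2 for type I interferon, inflammasome and autophagy machinery, and 1 and 0 for autophagy receptors. They were 2 and 9 for interferon gamma, 0 and 3 for complement and 1 and 9 for Müller glia homeostasis. By the mean of per-cell CPM they were 7 and 0 for NF-κB, 8 and 1 for early response, 7 and 3 for extracellular matrix, 5 and 4 for type I interferon and 4 and 1 for cell cycle. They were 3 and 1 for NRF2 targets, 3 and 3 for unfolded protein and neurogenic reprogramming, 2 and 0 for heat shock and 2 and 4 for inflammasome. They were 2 and 8 for interferon gamma, 1 and 2 for cholesterol synthesis, 1 and 3 for glycolysis, 0 and 3 for autophagy receptors and 1 and 16 for Müller glia homeostasis. After free RNA was taken away they were 7 and 1 for NRF2 targets, 1 and 8 for type I interferon, 2 and 6 for glycolysis, 2 and 4 for cholesterol synthesis and 1 and 4 for autophagy receptors. With cells thinned they were 1 and 17 for Müller glia homeostasis.

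**Figure D3:**
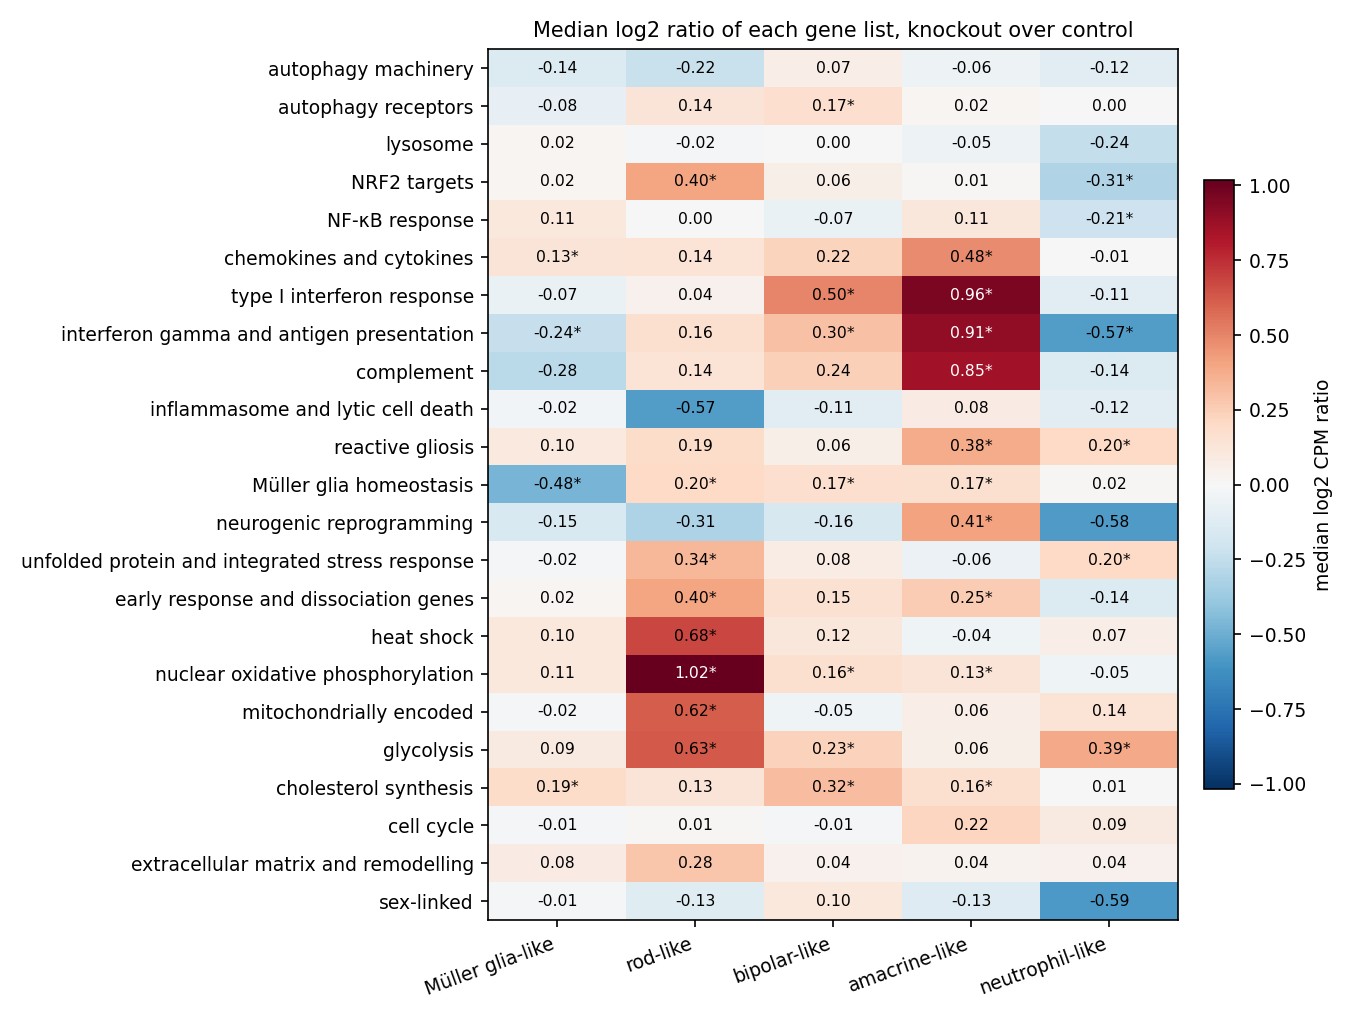
Median log2 CPM ratio of each gene list, knockout over control library, in 5 cell classes (columns), with colour from blue (lower in the knockout library) to red (higher) and a star where the median stood at or outside percentiles 2.5 and 97.5 of matched random lists. Müller glia homeostasis stands at -0.48 in Müller glia-like cells and the type I interferon response at 0.96 in amacrine-like cells.

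The same lists in other classes asked whether a difference was particular to Müller glia. Of 92 pairs of list and class, 31 stood apart. Interferon genes were higher in amacrine-like cells of the knockout library, inhibitory interneurons outside the Cre driver's target. Of 27 type I interferon genes 22 were higher and 0 lower (median 0.96, percentile 100), and of 29 interferon gamma and antigen presentation genes 21 were higher and 0 lower (median 0.91). In amacrine cluster 12 alone the interferon gamma median was 0.29 (0.01 to 0.63), inside the band, and in cluster 19 alone 0.36. Monocyte and macrophage marker RNA was higher in the same class, at 24.2 against 16.5 CPM (1.46, 1.15 to 1.88), and erythroid marker RNA at 360 against 149 CPM, most of it in 1 cell of each library. B2m stood at 110 against 58.7 CPM (1.88, 1.66 to 2.13). The interferon-induced GTPase Iigp1 was the largest ratio of all eligible genes in this class (7.29, 5.24 to 10.4), with 470 UMIs in 89 knockout cells. Complement (6 of 9 higher, median 0.85), chemokines and cytokines (0.48), neurogenic reprogramming (0.41), reactive gliosis (0.38), early response (0.25), Müller glia homeostasis (0.17), cholesterol synthesis (0.16) and nuclear oxidative phosphorylation (0.13) also stood above the band. With free RNA taken away, complement (0.64, over 4 members still measured) no longer stood apart and the chemokine and cytokine median came to -0.00188 over 8. The medians of type I interferon (1.94), interferon gamma (2.88), reactive gliosis (0.69) and Müller glia homeostasis (0.54) came out larger, over 21, 24, 7 and 14 members still measured. The subtraction removed 16.0% of control and 11.7% of knockout UMIs of this class, so it can raise ratios by itself. Other named genes of amacrine-like cells were the calcium buffer Pvalb (6.28) and Lama3 (5.49), and, among the smallest ratios, Ghrh (0.119, with 48 of 84 control UMIs in 1 cell), Zfp541 (0.412) and the monoamine carrier Slc18a2 (0.421, with 43 of 147 in 1 cell).

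Bipolar-like cells showed a smaller difference of the same direction: 10 of 26 type I interferon genes were higher and 2 lower (median 0.50), and 8 of 28 interferon gamma genes were higher and 2 lower (median 0.30). Cholesterol synthesis (0.32), glycolysis (0.23), autophagy receptors (0.17), Müller glia homeostasis (0.17) and nuclear oxidative phosphorylation (0.16) stood above the band as well. With free RNA taken away only the interferon lists and glycolysis of these did, with interferon gamma at 1.05 over 10 members still measured, and cholesterol synthesis turned to -0.74 over 9. Without the top 5 cells of each gene, autophagy receptors and Müller glia homeostasis (both 0.16) lay inside the band. The largest ratios were of BC028528 (12.5), Ppp1r17 (4.03) and Pcolce (2.63) and the smallest of the adhesion gene Kirrel3 (0.241), H2-Q7 (0.399) and Pvt1 (0.436). Rod marker RNA in bipolar-like cells had a ratio of 0.435, and in amacrine-like cells 0.238, while Müller glia marker RNA in bipolar-like cells was higher in the knockout library (1.27, 1.16 to 1.39).

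In rod-like cells 35 of 44 nuclear oxidative phosphorylation genes were higher and 0 lower (median 1.02), 10 of 12 heat shock genes (0.68), 10 of 20 glycolysis genes (0.63) and 10 of 13 mitochondrially encoded genes (0.62). NRF2 targets (0.40), early response genes (0.40), the unfolded protein response (0.34) and Müller glia homeostasis (0.20, and 0.01 without the top 5 cells of each gene) also stood above the band. With cluster 1 joined to the rods, homeostasis turned to -0.16, NRF2 targets (0.19) lay inside the band, and type I interferon (-0.65, 14 of 27 lower), interferon gamma (-0.54) and inflammasome genes (-0.58) stood below it. The largest ratios were of the heat shock genes Hspa1b (4.31) and Hspa1a (4.09) and of Lin7b (3.45), and the smallest of Fndc1 (0.0653, from 2 knockout UMIs), Ctdp1 (0.179) and Rpgrip1l (0.206). These sums came from 3686 control and 546 knockout cells of low depth. Cluster 0 held most rod-like cells of both libraries (80.7% of control and 61.7% of knockout), but the makeup of the class differed. Cluster 2 held 17.1% and 28.2%, and cluster 21, led by Ccl12 and Ccl5, held 2.20% and 10.1%. The medians of this class pool over these unlike mixes. In rod-like cells marker RNA of Müller glia had a ratio of 1.17 (1.02 to 1.35), that of neutrophils 0.676 (0.616 to 0.740), that of monocytes and macrophages 0.518 (0.361 to 0.725) and that of the lens 0.473 (0.230 to 0.876). Haemoglobin RNA was at 12354 CPM in knockout rod-like cells, 96.4% of it in 2 cells.

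In neutrophil-like cells 0 of 27 interferon gamma and antigen presentation genes were higher and 12 lower (median -0.57), while the type I interferon list lay inside the band (1 of 31 higher, 4 lower, median -0.11) but below it without the top 5 cells of each gene (0 of 30 higher, 5 lower, median -0.33). In the same class marker RNA of rods (0.243), monocytes and macrophages (0.794) and the lens (0.0378) was lower, and that of Müller glia (1.31, 1.18 to 1.46) and erythroid cells (11.1, 6.75 to 19.2) higher. NRF2 targets (-0.31) and the NF-κB list (-0.21) also stood below the band, and glycolysis (0.39, 8 of 18 higher), reactive gliosis (0.20) and the unfolded protein response (0.20) above it. Without the top 5 cells of each gene, NRF2 targets lay inside the band and the unfolded protein median was -0.0434. Once free RNA was taken away, the NF-κB list lay inside it, and interferon gamma (-0.87), glycolysis (1.11) and the unfolded protein response (0.57) stood further from 0, over 25, 14 and 8 members still measured. The cystatin genes Cstdc5 (12.9, with 197 of 560 knockout UMIs in 1 cell), Csta2 (5.73) and Stfa2 (5.38) were the largest ratios, and Saa3 (0.243), Eya3 (0.337) and Mylip (0.364) the smallest. Cluster 0 of the non-neuronal cells held 75.3% of control and 97.0% of knockout neutrophil-like cells. No test compared one class with another.

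Some lists inside the band in these classes left it under an alternative. Lists left with under 7 members are not given. With free RNA taken away, NRF2 targets (0.29) stood above it and extracellular matrix (-0.23) below it in amacrine-like cells. Lysosome (-0.20), unfolded protein (-0.34) and heat shock genes (-0.45) stood below it in bipolar-like cells. So did lysosome (-0.30) and early response genes (-0.44) in neutrophil-like cells. Without the top 5 cells of each gene, reactive gliosis (0.32) and early response genes (0.23) in bipolar-like cells, cholesterol synthesis (0.02) in rod-like cells and mitochondrially encoded genes (0.24) in neutrophil-like cells stood above it. Lysosome genes (-0.33) in neutrophil-like cells stood below it. In every class, leaving out 5 cells per library takes a larger part of the library with fewer cells, which can shift medians by itself.

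The last comparison was of Müller glia-like cells clustered on their own, as the study did. There were 5 subclusters, and the libraries shared 49.6% of their distribution over them. Subcluster 2 held the largest share of control cells (38.7%, 34.0 to 43.6, against 2.72% of knockout cells) and subcluster 0 that of knockout cells (56.0%, 51.8 to 60.0, against 10.2%). Subcluster 1 held 19.4% and 23.98%, subcluster 3, of shallow cells, 18.6% and 13.1%, and subcluster 4, rich in rod RNA, 13.1% and 4.25%. The genes that defined subcluster 2 included Prkag3, Hes5, Etnppl, Shisal2b, Agmo, BC055402 and Car14, which are also among the smallest ratios between the libraries, and those of subcluster 0 included Ccl20, Mmp3 and Cxcl9, among the largest. The subclusters and the gene differences therefore overlap. Subcluster 0 held 329 knockout and 42 control cells, and subcluster 2 held 160 control and 16 knockout cells, so this overlap is largely built in. Ccl20 and Cxcl9 also rested on few cells and do not mark subcluster 0 as a whole. Within subcluster 0 alone 20 and within subcluster 1 alone 17 of the 24 named genes stayed at least 1.5-fold on their side. The subclusters are given by number and not compared as cell types.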

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

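The 4 tests on the rod share in this part were chosen only after that share was seen. Some groups of cells outside the classes compared had a larger share in the knockout than in the control library. The unnamed cluster 9, closest to amacrine cells, held 5.06% of knockout and 1.80% of control cells, the bipolar-led cluster 13 held 3.95% and 1.18%, and the amacrine-led cluster 14 held 3.30% and 1.24%. Among non-neuronal cells, the unnamed cluster 10, led by Müller genes with the neutrophil gene S100a8 among them, held 1.31% of knockout and 0.218% of control cells. The cell filter left out 10.8% of knockout barcodes and 4.79% of control barcodes.

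These neuron clusters were larger in the library that held fewer rods, and the lower rod share is the pattern weighed here. Rods broken before capture, with their RNA left in the suspension, would raise rod RNA in other cells; the highest ratio of rod marker CPM among Müller glia-like, amacrine-like, bipolar-like and neutrophil-like cells was 0.435 (0.422 to 0.448), though RNA washed away before loading would leave no such trace. The cell filter does not account for it: counting every knockout barcode it left out as a rod gave 29.9% (28.7 to 31.2) of knockout barcodes for rods and the rod-led cluster 1, under a bound of 32.4%, which is 50% of the control value. Cone-like cells per bipolar-like cell were at 0.540 (0.399 to 0.731) of the control value, and rods and cells of cluster 1 per cone-like cell at 0.209 (0.156 to 0.279). These intervals cover counting error only, and with 1 library per group the spread of such yields between pools is not known, so broken rods, a loss of rods alone, a lower yield of the whole photoreceptor layer and an effect of genotype, Cre or 4-hydroxy-tamoxifen stay open.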

How the results depend on the processing

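The settings chosen only after the data were seen were the highest Scrublet scores left out, the top 5 cells of each gene left out, subcluster 1 alone and rods joined with cluster 1. Rod-like cells had the lower and Müller glia-like cells the higher share in the knockout library under every setting run, though the values moved. With the stricter cell filter the Müller glia-like shares were 9.89% (control) and 15.6% (knockout) and the rod-like shares 18.5% and 4.64%. Over neurons and glia alone they were 7.66% and 18.4%, and 68.3% and 17.1%, by the smaller denominator. At resolution 0.5 the control Müller share was 4.36% and the rod shares 68.1% and 21.5%; with the per-cell marker call these were 4.52%, 74.5% and 22.8%. Rod shares were 49.6% and 10.4% with 20 principal components, and 68.1% and 21.4% with cluster 1 joined. Atg5 had ratios from 0.804 to 1.04.

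All 24 named genes stayed at least 1.5-fold on their side under 8 settings of the cells and scaling. TMM scaling is among these, but its common log2 shift of 0.20 could not have brought any of the 24 within 1.5-fold. Scrublet calls left out is not counted, since it kept the same 413 control and 588 knockout cells. Of the 24, 22 stayed so with the per-cell marker call and without the top 5 cells, 20 in subcluster 0 and 17 in subcluster 1. With a minimum of 300 UMIs, 11 of the 24 remained among the largest and smallest ratios, since genes under that minimum can no longer be named. The count of lists apart in Müller glia-like cells, 4 in the main values, was 11 with the per-cell marker call, 9 in subcluster 0, 14 in subcluster 1, 9 with the mean of per-cell CPM and 9 with free RNA taken away. Müller glia homeostasis stayed apart in 12 of 12 settings (medians -0.61 to -0.24), chemokines and cytokines in 9, cholesterol synthesis in 8 and interferon gamma in 4. For homeostasis, the minimum of 100 UMIs kept the same 32 members and median, and taking free RNA away could move the median little. TMM scaling, the 2-fold threshold and Scrublet calls left out cannot move a percentile here and are not counted. With free RNA taken away, which was not done for rods, 31 of 68 pairs of list and class stood apart, against 23 of the same pairs in the main values.

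Directions turned as follows, and the cause was not tested. The ratios within subclusters have no interval and may rest on few UMIs. With the per-cell marker call, ratios were 0.585 for Mmp3, 0.808 for Spp1 and 0.973 for Ccl2, and the cholesterol synthesis median was -0.0397. In subcluster 0 they were 0.420 for Spp1, 1.32 for Gpc5, 1.37 for Hes5, 1.66 for Fabp5, 0.688 for Gfap and 1.24 for C3, with cholesterol synthesis at -0.0542. In subcluster 1 they were 0.196 for Mmp3, 1.47 for Etnppl, 1.76 for Shisal2b, 11.5 for Hes5, 1.47 for Agmo, 1.01 for Car14, 1.19 for Abca8b, 0.728 for Gfap, 0.612 for Vim, 0.839 for Ccl2 and 0.939 for Cxcl10, with chemokines and cytokines at -0.13 and cholesterol synthesis at -0.24. Resolution 0.5 gave 0.997 for Gfap and 1.00 for C3. TMM scaling gave 1.00 for Lcn2, 1.10 for B2m and 1.02 for C3, by its common shift. The mean of per-cell CPM gave 1.19 for Lcn2, 1.06 for B2m and 0.946 for Ddx3y, and thinning 1.04 for C3 and 0.962 for Ddx3y. With free RNA taken away, B2m was 1.01 and C3 1.00, cholesterol synthesis in bipolar-like cells -0.74 and chemokines and cytokines in amacrine-like cells -0.00188. Without the top 5 cells, Gpc5 was 4.78, with no control UMI left, and the unfolded protein list in neutrophil-like cells -0.0434. With cluster 1 joined, Müller glia homeostasis in rod-like cells was -0.16. Depth limits the genes of under 100 UMIs and the classes of under 100 cells.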

Other observations

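The values per thinned cell, the small classes, the members named in amacrine-like and rod-like cells, the single amacrine clusters and the tests with the Müller glia profile and with the monocyte and macrophage profile were chosen only after the data were seen. The Müller libraries differed in how their cells were spread. With each cell thinned to 5000 UMIs (272 control and 510 knockout cells, leaving out 141 and 78 shallower ones), Mt1, a metal-binding stress protein, had a median of 49 UMIs per cell in the control and 149 in the knockout library, with lower quartiles of 6 and 94.2. Timp1 had medians of 12 and 27.5. Lcn2 had medians of 28 and 80 but upper quartiles of 212 and 182, so the typical knockout cell held more Lcn2 although the pooled CPM (27187 and 23859) was higher in the control library. Glul went the other way at its upper end, with medians of 5 and 4 and upper quartiles of 13 and 6.

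Interferon genes went different ways in different cells. Leaving out the top 5 cells takes 5 from each library, and so a larger part of the library with fewer cells. The medians without those cells can shift for that reason alone. In retinal ganglion-like cells (39 control, 80 knockout) 22 of 23 type I interferon genes were higher in the knockout library and 0 lower, with a median log2 ratio of 1.72 (1.27 to 1.93), and 2.84 over 16 without the top 5 cells of each gene. In horizontal-like cells the median was 0.19 (-0.07 to 0.36), and 0.45 over 11 without those cells. In cone-like cells it was -1.64 (-2.35 to -0.92) over 7 genes, and -0.25 over 3 without those cells. In endothelial-like cells it was 0.23 (0.17 to 0.33), and 0.10 over 30 without them, and in monocyte and macrophage-like cells (94 and 51) -0.51 (-0.60 to -0.39), with 14 of 32 lower and 0 higher, and -0.64 over 30 without them. Within amacrine-like cells the effector genes Ifit1 (162 against 76.3 CPM), Ifit3 (133 against 51.9 CPM), Oasl2 (123 against 63.1 CPM) and Rsad2 (23.3 against 3.52 CPM) were higher. Isg15, also of the type I list, was not higher beyond counting error (14.8 against 12.3 CPM, ratio 1.20, 0.899 to 1.63). Of the interferon gamma list, H2-K1 (1.23), Psme1 (1.35) and H2-D1 (1.44) stayed under 1.5-fold. Ifngr2, a receptor chain for interferon gamma, was alike (17.6 against 19.2 CPM). In rod-like cells the oxidative phosphorylation genes Ndufa4 (852 against 349 CPM) and Atp5b (531 against 275 CPM) and the glycolytic Gapdh (1925 against 637 CPM) were higher; over rods joined with cluster 1 the oxidative phosphorylation median was 0.94, with 36 of 44 higher, and the type I interferon median was -0.65, with 2 of 27 higher and 14 lower.

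The lower homeostasis list in Müller glia-like cells was set against 2 technical explanations. If the greater depth of knockout cells were the cause, thinning was predicted to bring the median (-0.48) nearer to 0 than -0.24. It came to -0.61 (-0.68 to -0.49). Drawing UMIs at random leaves the expected CPM of a cell unchanged. Thinning could thus act only by weighting cells alike and by leaving out shallow ones, and cannot decide on depth. If RNA from other cells were the cause, taking its profile away was predicted to bring the median past the same bound. The median stayed at -0.47 (-0.53 to -0.40). Müller marker RNA is scarce in other cells, at 520 CPM in control amacrine-like against 8099 CPM in control Müller glia-like cells. The subtraction removed 32.5% of control and 35.8% of knockout UMIs. The median could therefore move little, and this value does not decide on RNA from other cells. A different makeup of subclusters was not tested in this way and stays open. Subcluster 2 held 38.7% of control and 2.72% of knockout Müller glia-like cells. Its Glul stood at 3220 CPM in the control cells and 755 CPM in the 16 knockout cells. Within subclusters 0 and 1 alone the list's medians were -0.25 and -0.24. No biological explanation was tested, and the design cannot separate Atg5 loss from Cre, 4-hydroxy-tamoxifen, the makeup of each pool or the strength of the injection.

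The higher type I interferon list in amacrine-like cells (median 0.96) was set against RNA from elsewhere and a different makeup. The median was 1.31 (1.21 to 2.00) with the profile of all other cells taken away. Over the 21 of 27 members still measured after it, the median was 1.94. That profile was scaled on rod markers (ratio 0.238 in these cells) and removed 16.0% of control and 11.7% of knockout UMIs. It can therefore raise ratios by itself, and its values do not decide on RNA from all other cells. With the Müller glia profile taken away until Lcn2 fell to 0 the median was 0.97 (0.88 to 1.14). That step removed only 0.53% of control and 0.87% of knockout UMIs. Müller marker RNA in amacrine-like cells was at 520 CPM (control) and 532 CPM (knockout). In Müller glia-like cells it was at 8099 and 6573 CPM. Scaling on Lcn2 may thus take away too little, and this value does not decide on RNA of Müller glia. The monocyte and macrophage profile was taken away until its markers, higher in amacrine-like cells of the knockout library (ratio 1.46), fell to 0. The median was then 0.96 (0.89 to 1.14), with 0.12% of control and 0.18% of knockout UMIs removed. The lowest of the 4 amacrine clusters, cluster 19, had 0.83 (0.56 to 0.99) over 16 measured members, above 0.48, the bound set for it. Cluster 12 had 0.91 (0.62 to 1.32) over only 9. The interferon gamma list did not hold in this way, with 0.29 (0.01 to 0.63) in cluster 12. For the type I list these values argue against RNA of monocytes and macrophages, as far as their markers track it, as the whole cause. They also argue against cluster makeup as the whole cause, for the members measured in each cluster. RNA of Müller glia and RNA from other cells at large stay open. No biological explanation was tested, and genotype, Cre, drug and injection stay open.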
